A study of Caenorhabditis elegans with 2 samples.

How the data were processed

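ChIP-seq of eGFP-tagged PHA-4 in mixed-stage C. elegans embryos was analysed from processed peak lists of 2 biological replicates. The antibody field of the labels reads pha-4, while the sample description names the tagged protein as the target, and the extraction protocol is not provided. All samples form 1 group, so the comparison between samples is replicate 1 against replicate 2, and each other comparison sets peaks against a genomic background. Per the labels the peaks were provided on 2 genome builds, and the ce11 lists were used, with the ce10 lists only where no annotation was needed.

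The authors called peaks on each replicate and on both replicates pooled, against 2 control files on ce11 and 1 on ce10, and derived the thresholded set by the irreproducible discovery rate (IDR) from the pooled and replicate lists. The peak caller, the aligner and the IDR threshold are not given in the sources used here. In the deposited lists the signal value of each peak is the caller's own signal against control reads, not scaled between lists. The deposited lists also hold the -log10 q of each peak as the caller gave it. Its highest value is shared by 1447 of the 2177 thresholded peaks, so it was not used for ranking. The replicate lists end at 30000 entries and include weak entries kept as background for IDR. The thresholded set is exactly the 2177 strongest pooled entries by signal (35.9 to 348), and on ce10 it holds 2262. No 2 entries were identical between the replicate lists. Read counts were not used here, the depth per replicate is unknown, and intervals cover counting of peaks or genes only. Control samples were not analysed here.

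Positions were compared with the Ensembl release 115 annotation of the same assembly. A promoter ran from 1000 bp upstream to 200 bp downstream of any annotated 5' end of a protein-coding transcript, and summits outside it were assigned to coding sequence, untranslated region, intron or intergenic sequence in that order. Where a summit lay in several genes' windows, each gene counted as bound, which held for 478 of 1363 promoter peaks. Location and replicate overlap (1 bp or more, against the 2177 strongest entries of each replicate) were compared with 1000 random placements within chromosomes. The signal correlation took the strongest overlapping entry of each replicate, and its interval came from 1000 bootstrap resamples of peaks. Chromosome shares were tested by exact binomial tests against genome length.

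Motifs were searched on both strands in windows of 100 bp on each side of the summit and in windows of the same size centred 500 bp to a randomly drawn side, with exact McNemar tests. The 8 motifs and, separately, all 7-mers were adjusted by Benjamini-Hochberg. The dinucleotide shuffle used 100 sets, and the trend with peak strength 100000 permutations. Gene lists and biotypes with at least 20 genes were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05 over the 21 lists and the 6 biotypes. The 21 lists were pharynx regulators, pharyngeal muscle, pharyngeal gland and cuticle, intestine regulators, intestine effectors, body wall muscle, epidermis, neurons, germline, autophagy, stress response, ribosomal proteins, V-ATPase, ceh homeobox genes, nuclear receptors, bHLH genes, T-box genes, collagens, C-type lectins, chemoreceptors and histones, of which those from ribosomal proteins on were taken by gene-name prefix. The gene pqn-47, asked for in the gland and cuticle list, was not found in the annotation. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

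The lists, tests, windows, motifs and naming rule were set before the data were examined. Named genes were pha-4; the genes at the 25 strongest promoter peaks; for each list up to 4 members with the strongest thresholded promoter peak and the leading 2 in list order without one; the 5 genes with most peaks nearest to their 5' end; the 5 peaks with the largest rank difference between replicates in each direction; and the 10 7-mers with the smallest p. Exceptions are named as such where they occur.

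Alternatives were the stronger 1088 thresholded peaks, each replicate's 2177 strongest entries alone, the ce10 lists, reciprocal overlap of 50% or summits within 50 bp, all replicate entries, promoter windows of 500 and 2000 bp, motif windows of 50 bp, TGTTTRC in place of TRTTKRY, 6-mers and 8-mers, entries below the threshold as background, the nearest 5' end only, genes with any pooled peak as background, 10000 random lists matched on upstream distance in 20 bins, and peaks outside 25 kb of pha-4 and unc-119. Chosen after seeing the data were the rank classes (successive blocks of 2177 entries of the pooled and replicate lists) and the test between them, counting genes that share a peak once, summits outside protein-coding promoter windows (for the non-coding genes, with the protein-coding reference left as it was), and leaving out the rol-6 stretch.

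The methods were tested on simulated data. For the 7-mer scan, windows with no added site gave 0 calls among 8192, and 6 of 6 implanted 7-mers were recovered. Both sets of windows there were shuffles of the same flanks. The check therefore does not cover the difference in GC between real summits (45.0%) and flanks (36.0%). For the motif share, sites implanted in 19.9% of 2177 windows gave an excess of 19.1 points. For the gene lists, tested on 19973 genes, raised lists were called in 98.5% and unchanged lists in 0.588% of cases. The raised lists had 22 to 79 genes and a share far above background, with genes drawn independently. Power for shorter lists, smaller rises or genes that share peaks was not tested. For location, 100% of summits placed in promoters were found there, which their placement well inside the window fixed in advance. For the strength trend over 2177 peaks, 6% of simulations with no trend and 100% of those with a rise of 4 points per class were called.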

Results

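PHA-4, the FoxA-family transcription factor that specifies the pharynx of C. elegans, was mapped on chromatin by immunoprecipitation and sequencing (ChIP-seq). The material was whole embryos of mixed stages and pooled sexes from strain OP37, whose integrated array wgIs37 supplies PHA-4 fused to eGFP. There were 2 biological replicates, each from a separate biosample, in 1 group, and the labels give no control group. Each replicate list held 30000 entries, the list called on both replicates together (the pooled list) held 21931, and the thresholded set derived from these lists held 2177 peaks. No read totals are given in the sources used here, so the depth of each replicate is unknown. Signal values served to rank peaks and to describe them within a list. Where signals of the 2 replicates are set side by side, they are not scaled to each other. Intervals on shares of peaks or genes are exact binomial intervals for counting error, and tests across peaks or genes describe where peaks lay, not error between replicates.

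The replicates were compared to ask how far the strong sites of one were strong in the other. Both placed their strongest peaks at many of the same sites, among them the promoters of the ribosomal protein genes rpl-3, rpl-20, rps-1 and rpl-15. Of the 2177 thresholded peaks, 80.6% overlapped one of the 2177 strongest entries of replicate 1, 82.1% one of replicate 2, and 64.1% one of each. Random placement within chromosomes gave 1.13% for replicate 1 and 1.21% for replicate 2, with a two-sided empirical p of 0.002 for the observed overlap, the smallest that 1000 placements can give. The thresholded set was itself derived from both replicates, so the 2 lists were also compared directly: 64.4% of the 2177 strongest entries of replicate 1 overlapped those of replicate 2, against 1.22% for random placement, and 35.1% of all 30000 overlapped an entry of replicate 2, against 15.6%.

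Peak strengths were moderately correlated between replicates. Across the 2153 thresholded peaks with an entry in both replicates, Spearman's rho of the signals was 0.355 (bootstrap interval over peaks 0.313 to 0.392) and Pearson's r of log2 signals was 0.386. Among the stronger 1088 peaks rho was 0.236. Both sets were cut by pooled signal, to which both replicates contribute. Such a cut can lower rho, so these values hold for the selected peaks only. The median signal was 24.9 in replicate 1 and 31.5 in replicate 2, with a median log2 ratio of replicate 2 over replicate 1 of 0.33 (SD 0.79 across peaks). The largest rank differences towards replicate 1 were 5 peaks at rol-6, a cuticle collagen gene, on chromosome II. Several of these peaks had the same replicate 1 signal of 127, the strongest there. Each peak was given its strongest overlapping replicate 1 entry, so the shared value does not show whether they are separate sites. Replicate 2 had no entry. The largest towards replicate 2 lay near kin-36 (11.4 in replicate 1, 75.7 in replicate 2), Y67D8A.2 (6.88 and 60.6), the chemoreceptor gene sre-23 (11.4 and 74.4), F57B1.6 (no entry and 53.1) and pha-4 itself (14.5 and 93.6).

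**Figure D1:**
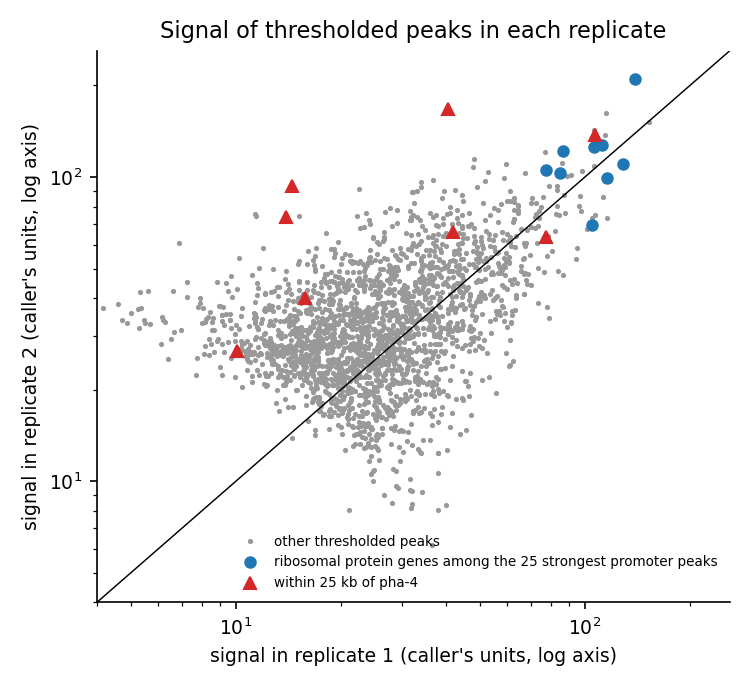
Signal of each thresholded peak in replicate 1 (x axis, log scale, the caller's units) and replicate 2 (y axis, log scale); each point is a peak found in both, the line marks equal signal, blue circles are peaks at ribosomal protein genes among the 25 strongest promoter peaks and red triangles are peaks within 25 kb of pha-4. Spearman's rho across the 2153 peaks was 0.355, and the pha-4 peak at rank 19 had 40.5 in replicate 1 and 167 in replicate 2.

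Peak positions were set against gene annotation to ask where along genes the factor lay. PHA-4 peaks lay mainly in promoters: 1363 of 2177 summits (62.6%) fell in the window from 1000 bp upstream to 200 bp downstream of a protein-coding 5' end, against 25.7% of random placements, a ratio of 2.43. Coding sequence held 11 summits (0.505% against 18.9%), untranslated regions 10 (0.459% against 2.66%), introns 310 (14.2% against 27.8%) and intergenic sequence 483 (22.2% against 24.9%). The empirical p was 0.002, the smallest that 1000 placements can give, for promoters, introns, untranslated regions and coding sequence, and 0.00599 for intergenic sequence. The intergenic deficit did not pass in replicate 2 alone (24.1%, p = 0.392 by permutation of positions) or with a promoter window of 500 bp upstream (29.2% against 29.7%, p = 0.631). The pooled entries below the threshold lay in promoters at 33.3% (odds ratio 3.36, Fisher's exact p = 1.34e-153). The median distance from a thresholded summit to the nearest 5' end was 381 bp, and 49.8% lay within 500 bp upstream of one.

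Peaks were spread unevenly over chromosomes. Chromosome X held 458 peaks (21.04%, 95% interval 19.3 to 22.8) against 17.7% of the nuclear genome (exact binomial adjusted p = 0.000116). Chromosome III held 17.1% against 13.7% (exact adjusted p = 3.34e-05) and chromosome I 17.3% against 15.03% (adjusted p = 0.00597). Chromosome V held 13.3% against 20.9% (exact adjusted p = 4.98e-19), chromosome IV 15.2% against 17.4% (adjusted p = 0.00676), and chromosome II 16.08% against 15.2% (adjusted p = 0.283). Against the entries below the threshold, of which 21.4% lay on X, the direction on X turned (Fisher's exact adjusted p = 0.762), and the calls on I, III and IV were lost (exact adjusted p = 0.265, 0.110 and 0.642) while that on V stayed (exact adjusted p = 0.000589). Among the stronger 1088 peaks the calls on I and IV were lost (exact adjusted p = 0.112 and 0.167).

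The strongest single peak lay at -281 bp from the 5' end of rpl-3, at III 3867473 to 3867676 on ce11, with a pooled signal of 348 (139 in replicate 1 and 210.5 in replicate 2). The second lay in an intron near Y111B2A.12 at III 12612542 to 12612785, with a signal of 309. The 25 strongest promoter peaks carried 41 genes, and 9 of these peaks lay at a ribosomal protein gene: rpl-3, rpl-20 (with Y17G9B.5, 240.3), rps-1 (with the translational repressor gene ifet-1, 240.0), rpl-15 (with K11H12.8, 234.5), rps-19 (with hsr-9, 216), rps-12 (with ska-3, 209), rpl-12 (with lin-54, 188), rpl-35 (184) and rps-28 (with Y41D4B.4, 177). The other peaks lay at the eIF5A gene iff-2 (with F54C9.14, 233), drr-2 with set-16 (174), the translocon genes sec-61.G (with F32D8.13, 199) and sec-61.B (with trap-3, 183), the chaperone gene hsp-3 (195), hsp-110 with the proteasome subunit gene rpn-3 (216), and dnj-14 with glit-1 (248). The rest were C06B8.7 (276), tasp-1 with K01G5.10 (249.8), the Gq alpha gene egl-30 with C53H9.4 (198), serp-1.1 (194), pha-4 (190.0), eelo-2 (189), Y39B6A.43 (184), nspc-17 (175) and nhl-2 with tag-340 (174). TRTTKRY occurred in 14 of the 25 summit windows, TGTTTRC in 4 and GAGAGA in 8.

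The pha-4 gene was bound at several places. Within 25 kb of the gene (V 20753052 to 20760317, plus strand) lay 8 thresholded peaks. The strongest lay at -3821 bp from the nearest pha-4 5' end, at V 20749101 to 20749386, rank 9, with signals of 107 in replicate 1 and 138 in replicate 2. A peak at V 20756739 to 20756897, in the promoter window of an internal 5' end, ranked 19. Because the strain carries additional pha-4 copies on the array, reads from the gene and from the array were not separated here. By number of thresholded peaks nearest to the 5' end, the leading genes were rol-6 (8), egl-27, an MTA-like gene (7), lin-42, the Period homologue (6), F57G12.1 (5) and din-1, a nuclear receptor corepressor gene (5). The 8 at rol-6 were not all in separate intervals.

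**Figure D2:**
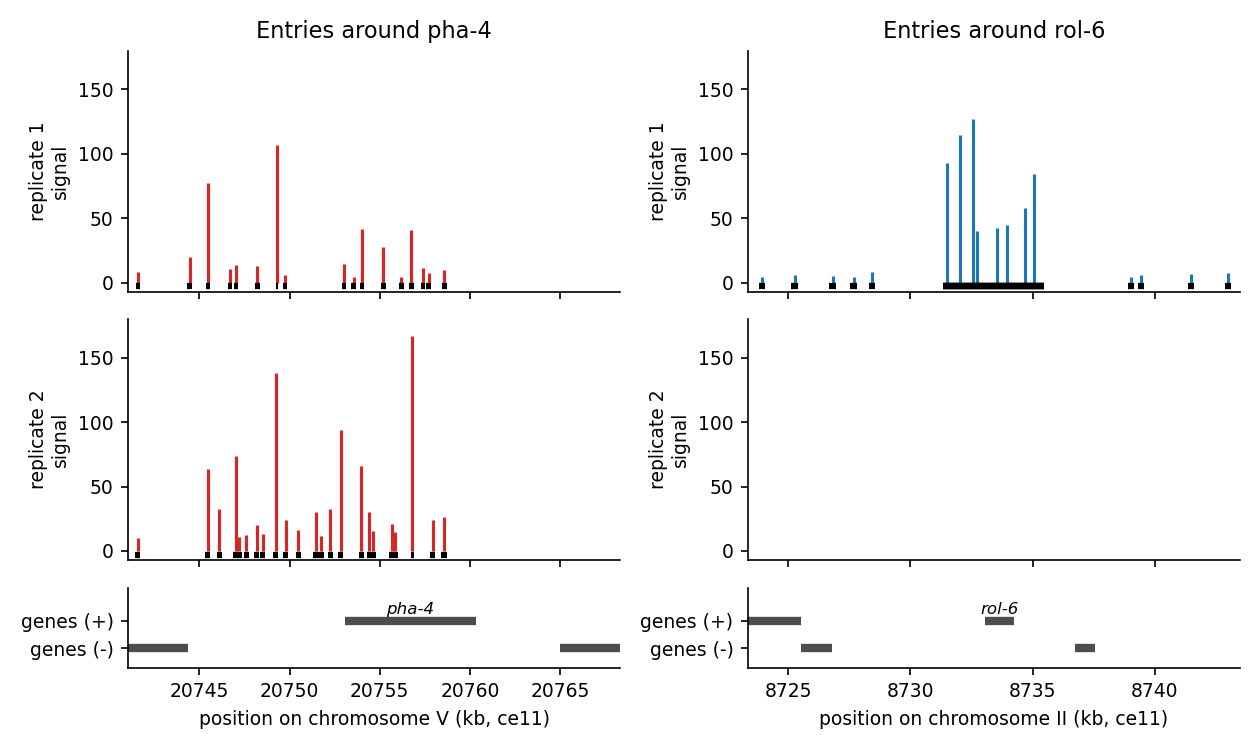
Signal of each replicate's entries (y axis, the caller's units, same scale in all 4 signal panels) against position in kb on ce11, around pha-4 on chromosome V (left) and rol-6 on chromosome II (right); black bars under the lines give the entries' extent, and the lowest panels give protein-coding genes by strand. At rol-6 replicate 1 had 8 adjoining or overlapping entries with signals of 40.1 to 127 and replicate 2 had none.

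Sequence at summits was compared with sequence 500 bp away to ask which motifs marked the sites. TRTTKRY, the published PHA-4 consensus, stood in 61.1% of summit windows (59.0 to 63.1) and 46.6% of flank windows (exact McNemar adjusted p = 5.31e-21). The stricter FoxA-type site TGTTTRC stood in 20.6% against 6.16% (exact adjusted p = 1.06e-43). The largest excess over flanks belonged to the comparison motif GAGAGA, at 47.7% against 10.6% (exact adjusted p = 2.40e-152). TCACAC, a T-box site, stood in 13.9% against 7.12% (exact adjusted p = 1.66e-12), CAAGTG, an NK-2 site, in 13.6% against 7.44% (adjusted p = 3.04e-11), TTCCCGCC, an E2F site, in 1.65% against 0.689% (adjusted p = 0.00526) and the E-box CANNTG in 57.9% against 54.02% (adjusted p = 0.00974). The GATA-type site TGATAA was scarcer at summits, at 6.89% against 18.2% (exact adjusted p = 1.15e-29). Summit windows had 44.99% GC and flanks 36.0%. Dinucleotide-shuffled summit windows held TRTTKRY at 35.7% on average (SD 0.908 over 100 sets), and 0 of 100 sets reached the observed share. In shuffled windows TGTTTRC stood at 6.96% and GAGAGA at 18.2%, above its share in flanks, and 0 of 100 sets reached the observed share of either. TCACAC, CAAGTG, TTCCCGCC, CANNTG and TGATAA were not set against shuffled windows. Whether the GC difference accounts for their contrasts with flanks was therefore not tested.

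**Figure D3:**
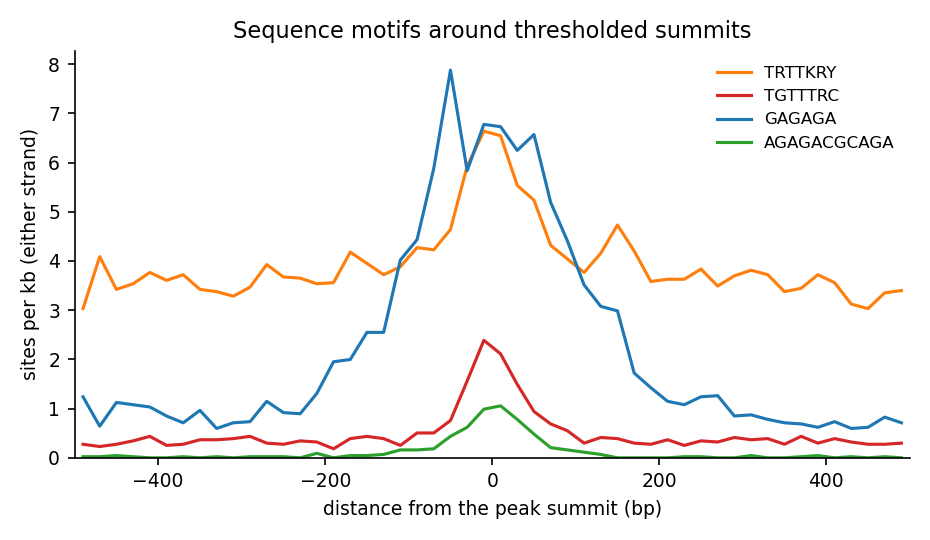
Sites per kb on either strand (y axis) against distance from the summit in bp (x axis, bins of 20 bp) for TRTTKRY, TGTTTRC, GAGAGA and AGAGACGCAGA over the 2177 thresholded peaks. TGTTTRC reached 2.39 sites per kb beside the summit and TRTTKRY 6.64, while GAGAGA was raised over a wider stretch.

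A scan of all 8192 7-mers, each merged with its reverse complement, found 1726 more frequent at summits and 1434 less frequent after adjustment. The mean GC content was 63.96% for the more frequent 7-mers and 29.996% for the less frequent. The 10 with the smallest p were GA-repeat words and a GACGCAGA-type element: CTCTCTC (24.6% against 2.80%, exact adjusted p = 2.19e-104), GAGACGC (20.9% against 1.88%), CTGCGTC (20.99% against 1.98%), AGAGACG (21.3% against 2.11%), ACGCAGA (20.6% against 1.93%), AGACGCA (20.99% against 2.205%), AGAGAGA (23.6% against 4.23%), GAGAGAC (17.8% against 1.98%), CGAGAGA (16.8% against 2.07%) and ACTCTCT (15.5% against 2.30%). Of the 16 7-mers that match TRTTKRY, 6 were among the more frequent. Outside the naming rule and singled out after their values were seen, the FoxA-type words GCAAACA (13.5% against 3.90%, exact adjusted p = 1.13e-26) and GTAAACA (8.22% against 2.43%, adjusted p = 1.34e-16) stood at places 52 and 98. With 6-mers the count was 737, and with the stronger 1088 peaks it was 1114.

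Whether stronger peaks held TRTTKRY more often was asked over 5 classes of equal size. From the weakest to the strongest class the share was 61.6%, 63.9%, 60.1%, 61.8% and 58.0%, and no trend passed the test (r = -0.0268 across peaks, permutation p = 0.216). In the strongest 2177 entries of replicate 1 alone the trend was downward (r = -0.0684, permutation p = 0.00148), and in those of replicate 2 alone r was -0.0297 (permutation p = 0.170).

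Gene lists were used to ask which classes of promoter were bound. Of 19973 protein-coding genes, 1833 (9.18%) had a thresholded peak in the promoter window. Ribosomal protein genes, stress-response genes and histone genes had more bound promoters than other genes, and collagen, C-type lectin and chemoreceptor genes had fewer, by Fisher's exact test adjusted over the 21 lists. The lists of pharynx regulators, pharyngeal muscle and pharyngeal gland and cuticle did not pass in either direction in the thresholded set.

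Of 79 ribosomal protein genes, 62 (78.5%, 67.8 to 86.9) were bound, an odds ratio of 37.3 (exact adjusted p = 6.68e-48), with 63 in replicate 1 alone and 49 in replicate 2 alone (odds ratio 18.8). With each peak given to the nearest 5' end only, the odds ratio was 12.1 (exact adjusted p = 5.38e-21). The strongest were rpl-3, rpl-20, rps-1 and rpl-15, and rpl-10 and rpl-11.1 had no thresholded promoter peak. The 59 peaks concerned had a median signal of 90.4 against 54.1 for other peaks (Mann-Whitney p = 4.54e-11), and they held TRTTKRY less often, 32.2% against 61.9% (Fisher's exact adjusted p = 3.35e-05). Of 24 stress-response genes, 9 (37.5%) were bound, an odds ratio of 5.96 (exact adjusted p = 0.000694). These included the chaperone genes hsp-3 (195), hsp-90 (149), hsp-1 (114) and hsp-60 (106.0), while the superoxide dismutase genes sod-3 and sod-4 had no thresholded promoter peak. The stress-response call was lost in replicate 2 alone (odds ratio 2.95, exact adjusted p = 0.111) and when each peak went to the nearest 5' end only (odds ratio 3.73, adjusted p = 0.0646). Of 50 histone genes, 17 (34%) were bound, an odds ratio of 5.14 (exact adjusted p = 5.87e-06), by 10 distinct peaks. The strongest peaks were at his-67 and his-68 (146), his-37 (124) and his-32 (109), and his-1 and his-12 had none. With genes that share a bound peak counted once, the odds ratio for histones was 3.01 (exact adjusted p = 0.0166), a fall of over 1.5 times.

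Among cuticle collagens 4 of 156 were bound, namely col-38 (101), col-71 (52.7), col-2 (51.3) and col-8 (38.8), an odds ratio of 0.259 (exact adjusted p = 0.00666), with none at col-10 and col-101. This call was lost in replicate 2 alone (odds ratio 0.368, exact adjusted p = 0.0548) and among genes with any pooled peak (odds ratio 0.459, adjusted p = 0.374). Among C-type lectins 1 of 237, clec-140 (39.3), was bound, an odds ratio of 0.0414 (exact adjusted p = 3.45e-08), with none at clec-1 and clec-10. Each replicate alone had 2 of 237, an odds ratio of 0.0788 in replicate 1 (exact adjusted p = 1.61e-07) and 0.094 in replicate 2 (exact adjusted p = 4.06e-06). Among genes with any pooled peak that ratio was 0.129 (exact adjusted p = 0.0675). Among chemoreceptors 8 of 1219 were bound, an odds ratio of 0.0613 (exact adjusted p = 9.96e-40). Among genes with any pooled peak the ratio was 0.168 (8 of 147, exact adjusted p = 4.93e-09), and with a window of 2000 bp upstream 0.0987 (17 of 1219, exact adjusted p = 5.50e-45). The strongest were sre-23 (83.2), srh-16 (73.9), sri-5 (69.8) and sre-1 (52.3), with none at str-1 and str-10.

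Of the 17 pharynx regulators only pha-4 was bound (exact adjusted p = 1), and pha-2 and pha-1 had no thresholded promoter peak. Replicate 1 alone had 3 of 17, which turned the odds ratio from 0.618 to 2.01 (exact adjusted p = 0.423), and replicate 2 alone had 1. Of 14 pharyngeal muscle genes only the myosin gene myo-2 was bound (40.9, exact adjusted p = 1), not myo-1 or myo-5, and of 22 gland and cuticle genes 0 were, phat-1 and phat-2 included (adjusted p = 0.450). Gland and cuticle genes had 2 in replicate 1 alone and 1 in replicate 2 alone. Intestine regulators, with end-1 and end-3, had 0 of 8 (exact adjusted p = 1) and intestine effectors, with ges-1 and vit-1, 0 of 29 (adjusted p = 0.223). Body wall muscle had 5 of 25 (exact adjusted p = 0.171), the strongest being unc-52 (103.5), unc-112 (80.9), pat-4 (74.2) and lev-11 (64.6), with none at hlh-1 and unc-120. The list passed in replicate 2 alone (odds ratio 3.54, exact adjusted p = 0.0483). Autophagy had 5 of 25 (exact adjusted p = 0.171), the strongest being lgg-1 (107), epg-6 (54.9), lgg-2 (52.4) and atg-16.2 (49.6), with none at bec-1 and unc-51, and it passed in replicate 1 alone (odds ratio 3.66, adjusted p = 0.0232). The proton pump (V-ATPase) genes had 5 of 20 (exact adjusted p = 0.0936), the strongest being vha-1 (98.7), vha-12 (83.5), vha-15 (77.9) and vha-8 (69.1), with none at vha-10 and vha-11, and they passed in replicate 2 alone (odds ratio 4.80, adjusted p = 0.0181). Body wall muscle and V-ATPase also passed among the stronger 1088 peaks (exact adjusted p = 0.023 and 0.039), V-ATPase with a window of 500 bp upstream (exact adjusted p = 0.0418) and autophagy with 2000 bp (exact adjusted p = 0.0047).

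Epidermis had 2 of 24, rol-6 (133, with no entry in replicate 2) and vab-10 (81.4), and neither elt-1 nor lin-26. Neurons had 2 of 28, unc-33 (47.05) and snb-1 (46.9), and neither unc-119 nor rab-3. Germline had 2 of 31, mex-1 (99.2) and spo-11 (49.99), and neither pgl-1 nor pgl-3. The ceh homeobox genes had 2 of 63, ceh-38 (113) and ceh-39 (63.6), and neither ceh-1 nor ceh-10 (exact adjusted p = 0.235). The bHLH genes had 1 of 25, hlh-30 (36.2), and neither hlh-1 nor hlh-10, and the T-box genes, tbx-11 and tbx-2 included, had 0 of 18 (exact adjusted p = 0.649). Nuclear receptors had 23 of 269, led by nhr-56 (99.6), nhr-47 (88.3), nhr-1 (86.9) and nhr-49 (85.3), with none at nhr-10 and nhr-100. The adjusted p was 1 for epidermis, neurons, germline, bHLH genes and nuclear receptors. In replicate 2 alone epidermis and germline had 1 gene each and the ceh genes 4, while nuclear receptors had 24 in each replicate alone, with odds ratios of 0.917 in replicate 1 and 1.1 in replicate 2. None of these single-replicate values passed.

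**Figure D4:**
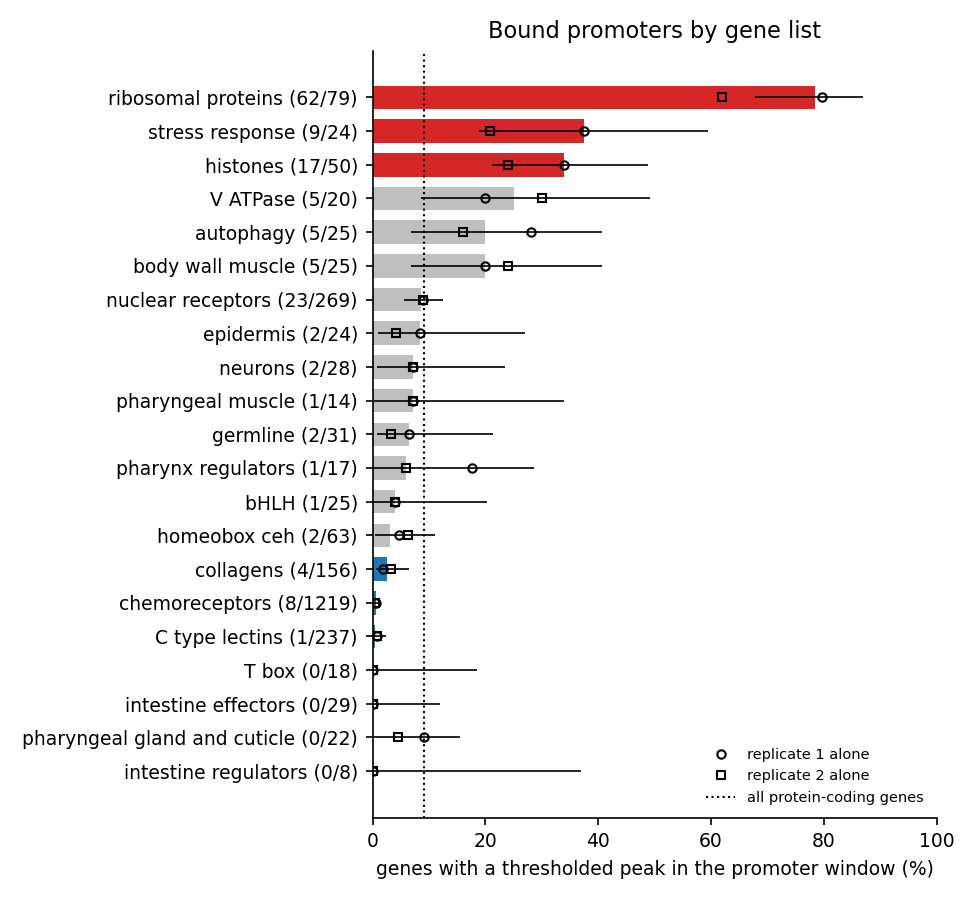
Share of each list's genes with a thresholded peak in the promoter window (bars, percent, with bound and total genes in brackets and exact binomial 95% intervals); circles and squares give replicate 1 alone and replicate 2 alone, and the dotted line marks 9.18% of all protein-coding genes. Red bars passed the adjusted test as higher and blue bars as lower, with ribosomal proteins at 78.5%.

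Lists were also counted over successive blocks of 2177 pooled entries by signal, a view chosen after seeing the data. The 3 pharynx lists merged, 53 genes, had a promoter entry at 2 genes (3.77%) in the thresholded block and at 16 (30.2%) in the next (odds ratio 5.87 against other genes, Fisher's exact p = 3.28e-07), with 6 and 9 genes in replicate 1 alone and 3 and 12 in replicate 2 alone, and ribosomal protein genes at 62 and 9 of 79. In the pooled blocks pha-4, which the array also carries, counts in both.

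**Figure D5:**
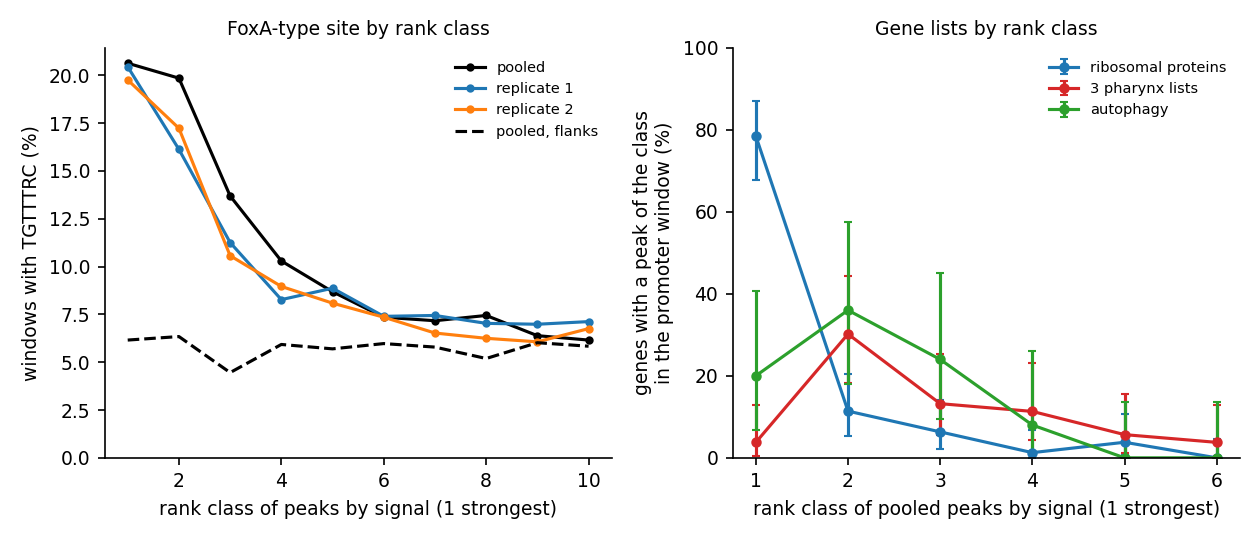
Left, share of summit windows with TGTTTRC (y axis, percent) by rank class of 2177 entries each (x axis, 1 strongest) in the pooled and replicate lists, with the flanks of pooled entries dashed. Right, share of genes with a promoter entry of each pooled rank class (y axis, percent, exact binomial 95% intervals) for ribosomal proteins, the 3 pharynx lists merged and autophagy; the pharynx lists stood at 3.77% in class 1 and 30.2% in class 2.

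Non-coding genes were compared with protein-coding genes in the same window. Small nucleolar RNA genes were bound at 108 of 346 (31.2%), an odds ratio of 4.49 (exact adjusted p = 2.03e-29), and 61 of the 108 only through peaks that also lay in a protein-coding promoter window. Transfer RNA genes were bound at 91 of 612 (14.9%), an odds ratio of 1.73 (exact adjusted p = 1.58e-05), and this call was lost in replicate 1 alone (odds ratio 1.19, adjusted p = 0.280) and among the stronger 1088 peaks (odds ratio 1.43, adjusted p = 0.0553). Pseudogenes were bound at 15 of 2128 (odds ratio 0.0703, exact adjusted p = 9.52e-62) and the ncRNA class at 605 of 7764 (odds ratio 0.836, adjusted p = 0.000343), a call lost in replicate 2 alone (odds ratio 0.999, exact adjusted p = 1) and with a window of 500 bp upstream (odds ratio 0.894, adjusted p = 0.052). MicroRNA genes (28 of 261, exact adjusted p = 0.465) and small nuclear RNA genes (11 of 129, adjusted p = 1) did not pass.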

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

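The tests in this part were chosen after the results were seen. They concern pooled entries below the deposited threshold, which the main comparisons do not use, taken as the next 2177 entries by signal (ranks 2178 to 4354).

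In that rank class 5 of 17 pharynx regulators (29.4%) had a promoter entry (odds ratio 5.62, Fisher's exact adjusted p = 0.0203), against 6.91% of other genes. Among these 5 was pha-4 itself, which the array also carries and which had a thresholded promoter peak too. Pharyngeal muscle had 5 of 14 (35.7%, odds ratio 7.49, exact adjusted p = 0.0131). Pharyngeal gland and cuticle had 6 of 22 (27.3%, odds ratio 5.06, exact adjusted p = 0.0163). Autophagy genes had 9 of 25 (36%, odds ratio 7.60, exact adjusted p = 0.000277). TGTTTRC stood in 19.8% of these summit windows and 6.34% of their flanks, where the thresholded peaks had 20.6% and 6.16%.

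Whether the pharynx lists differed between the thresholded peaks and the next rank class was tested on genes with an entry in just 1 of the 2 classes. The 3 pharynx lists merged had 1 such gene in the thresholded set and 15 in the next class, against 1758 and 1294 other genes (odds ratio 20.4, Fisher's exact p = 2.60e-05). Alone, gland and cuticle passed (0 and 6 genes, exact adjusted p = 0.0488), while pharynx regulators (0 and 4, exact adjusted p = 0.116), pharyngeal muscle (1 and 5, exact adjusted p = 0.210) and autophagy (4 and 8, exact adjusted p = 0.296) did not. Ribosomal protein genes went the other way (62 and 9, odds ratio 0.189, adjusted p = 1.37e-06), as did histones (16 and 2, exact adjusted p = 0.0488). The same test within each replicate gave, for the merged pharynx lists, 3 and 6 genes in replicate 1 (odds ratio 3.20, Fisher's exact p = 0.096), so the difference did not pass there, and 2 and 11 in replicate 2 (odds ratio 7.59, Fisher's exact p = 0.00297). Counting all genes with an entry, replicate 1 had 6 of 53 in its strongest 2177 entries and 9 in ranks 2178 to 4354 (odds ratio 3.11 against other genes, Fisher's exact p = 0.00494), and replicate 2 had 3 and 12 (odds ratio 4.53, Fisher's exact p = 6.69e-05). No pharynx list alone differed within a replicate, gland and cuticle having 2 and 1 genes in replicate 1 (exact adjusted p = 1) and 1 and 4 in replicate 2 (exact adjusted p = 0.535). Histones did not differ within either replicate (exact adjusted p = 0.321 and 0.535), and ribosomal protein genes differed in replicate 1 (exact adjusted p = 2.74e-06) but not in replicate 2 (exact adjusted p = 0.495).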

How the results depend on the processing

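Rank classes, genes sharing a peak counted once, summits outside coding promoters and the set without rol-6 were chosen after the data were seen; the other alternatives were planned. Among the main results 60 alternative values stayed on the same side of the test or at a similar count, 11 moved, 1 turned direction and 1 newly passed; for single lists 219 had the same call, some uncalled ones with an odds ratio on the other side of 1, 7 newly passed and 5 no longer did. A similar count need not mean the same lists: the 4 higher in pooled class 2 were the pharynx lists and autophagy. With entries below the threshold as background, the X share of 21.04% turned from above to below its reference. With the stronger 1088 peaks, rho was 0.236, the 7-mer count 1114 (1077 shared with the main set), 5 lists were higher and 1 biotype was raised. Nearest summits gave a rho of 0.398, and 6-mers a count of 737, out of fewer words tested. Genes with any pooled peak as background left 1 lower list. Class 3 gave 0 higher lists in replicate 1 and 1 in replicate 2. Summits outside coding promoters left 1 raised biotype, a fall built into that setting, which leaves the protein-coding reference unfiltered. The cause was not tested for the others, apart from the fewer words. Single replicates gave the following lowest and highest values: overlap 80.6% and 82.1%, promoter share 58.2% and 65.7%, X share 20.6% and 22.0%, TRTTKRY 59.9% and 62.7%, 7-mers 1629 and 1717, higher lists 4 and 4, lower lists 2 and 3, raised biotypes 1 and 2, and strength trend r -0.0684 (permutation p = 0.00148) and -0.0297. Rank classes aside, ribosomal proteins, histones and chemoreceptors kept their calls under each of their 11 alternatives, C-type lectins under 10, collagens and stress response under 9. Read depth is unknown, so a promoter with no entry is not shown to be unbound; body wall muscle did not pass with 5 of 25 genes (odds ratio 2.48) and passed with 6 of 25 in replicate 2 alone (odds ratio 3.54) and with 5 of 25 among the stronger 1088 peaks (odds ratio 4.86).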

Other observations

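Of the tests here, those of unc-119, of the motif near pha-4, of motifs at ribosomal protein promoters and of rol-6 were chosen after the results were seen, as were the genes, sequences and tests of the next 2 paragraphs except the shuffled windows.

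Genes of pharyngeal fate and function had promoter entries below the deposited threshold of 35.9, in the rank class that reaches down to a signal of 21.7. Among pharynx regulators these were ceh-34 (31.5), ceh-22, an NK-2 gene of pharyngeal muscle (26.4), hlh-6, a gland regulator (25.4), and ceh-32 (22.5). The gene pha-4, which the array also carries, had such entries too and counts among the 16 of 53 given below. Among pharyngeal muscle genes they were exp-2 (33.9), eat-18 (29.6), tnt-4 (25.9) and the myosin genes myo-5 (25.3) and myo-1 (22.8). Among gland and cuticle genes they were abu-13 (32.9), pqn-74 (29.1), lys-8 (27.1), abu-8 (26.8), pqn-13 (26.1) and abu-14 (26.1). None of 10000 random lists matched on upstream distance reached the 16 of 53 genes of the merged lists in ranks 2178 to 4354, against a mean of 3.38 (permutation p = 0.0002, the smallest these draws can give). Within replicate 1 alone the merged lists had 6 genes in the strongest 2177 entries and 9 in the next block, a difference that did not pass (Fisher's exact p = 0.096). In ranks 4355 to 6531 the merged lists had 7 of 53 (Fisher's exact p = 0.0133, and permutation adjusted p = 0.088 against matched lists): 4 of 17 regulators, 3 of 14 muscle genes and 0 of 22 gland and cuticle genes, none of which passed against matched lists (permutation adjusted p = 0.069, 0.126 and 1). Autophagy had 6 of 25 there (odds ratio 6.25, exact adjusted p = 0.00816), a call lost in replicate 1 alone (4 of 25, exact adjusted p = 0.103) and in replicate 2 alone (2 of 25, exact adjusted p = 0.499). Autophagy genes in ranks 2178 to 4354 included atg-2 (34.4), epg-8 (31.2), atg-9 (30.6) and atg-3 (28.2). The FoxA-type site TGTTTRC fell towards flank level with rank, from 19.8% in class 2 to 13.7% in class 3, 10.3% in class 4 and 6.16% in class 10, where flanks had 5.83%.

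An 11-base element, AGAGACGCAGA, assembled from 7-mers leading the scan of these same windows, so with no independent test, stood in 213 summit windows (9.78%) and 9 flank windows (0.413%). GAGAGA was commoner at summits outside promoters than inside, with 62.1% of intergenic, 53.9% of intronic and 41.2% of promoter summits (odds ratio outside against inside 2.02, Fisher's exact p = 4.99e-15). TRTTKRY showed a smaller difference (odds ratio 1.36, exact p = 0.000908), and TGTTTRC none that passed (odds ratio 0.989, p = 0.956). The share of summit windows with TRTTKRY lay 23.8 points above the 95th percentile of dinucleotide-shuffled sets, which argues against base composition as its whole source.

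Ribosomal protein, stress-response and histone promoters were bound more often than others. Random lists matched on upstream distance reached the observed counts in at most 0.03% of draws. Counts were 5.82, 4.15 and 2.29 times the matched means for ribosomal proteins, stress response and histones. Their median upstream distances were 557, 871 and 267.5 bp, against 1438 to 3333 bp for the pharynx lists, so long upstream regions were not at issue. The draws argue only against upstream distance as such as the whole source. They counted genes, and the 17 bound histone genes had 10 distinct peaks. All 3 lists stayed raised among genes with any pooled peak (odds ratios 14.7, 9.005 and 4.65 for ribosomal proteins, stress response and histones). Their excess was therefore not one of having any pooled entry alone. Thresholded peaks are the strongest entries of that same list, and having an entry does not grade accessibility. Generally accessible promoters therefore stay open as a source. At ribosomal protein promoters TRTTKRY was scarcer than at other peaks (odds ratio 0.292, exact adjusted p = 3.35e-05), which argues against more frequent use of that motif as the source of their excess. The scarcity was not particular to TRTTKRY: GAGAGA stood at 25.4% against 48.3% (odds ratio 0.364, Fisher's exact adjusted p = 0.00101). Against their own flanks TRTTKRY, TGTTTRC and GAGAGA did not pass there (exact McNemar p = 0.169, 0.754 and 0.134). TGTTTRC gave an odds ratio of 0.428, with a raw p of 0.0491, on which it was at the start judged as scarcer, and an adjusted p of 0.0654, on which its part stays open.

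Within 25 kb of pha-4 lay 19 entries below the threshold, 3.32 per 10 kb against a median of 1.80 around protein-coding genes. Extra pha-4 copies on the array may raise this background: its percentile of 90.8 is under the 95th set beforehand as the limit, but the Poisson interval of 11.4 to 29.7 entries takes in the 21.2 at that percentile, so, by a reading adopted after the result was seen, array copies cannot be told apart from a dense neighbourhood. Around unc-119, whose rescuing copy marks such arrays, the percentile was 67.5, and its interval of 6.92 to 22.2 around 13 entries also takes in the limit of 20.9. Binding by PHA-4 across its own upstream region would raise TRTTKRY there, and 6 of the 12 upstream entries held it (odds ratio 0.949, Fisher's exact p = 1), while 0 of 5 inside the gene and 0 of 2 downstream did, which brought the odds ratio over all 19 to 0.438 (Fisher's exact p = 0.108); the entries are too few to decide. With 1 group, no biological difference between samples was tested.

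At rol-6 replicate 1 had 8 adjoining or overlapping entries over 4129 bp (II 8731351 to 8735479), with signals up to 127. They were the 8 entries in its list wider than the median of 250 bp, and the widest entry of that list was 2456 bp. Replicate 2 had no entry between 8722703 and 8743596. None of the 8 thresholded peaks there had a replicate 2 entry, although that list reaches down to a signal of 5.25, which argues against binding common to both replicates. A candidate explanation is extra copies of rol-6 DNA in replicate 1, since rol-6 is a common marker in worm transformation. Copies would place summits in exons as well, and 2 of 8 lay there against 5.16% of 2169 elsewhere (odds ratio 6.12, Fisher's exact p = 0.0619). The test counts the 8 peaks as independent, but they adjoin, and those at ranks 89 and 1403 share the same interval. With these 8 peaks extra copies cannot be told apart from binding in replicate 1 alone. Without the stretch 3 lists were higher and 3 lower, as with it.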
